A study of Mus musculus with 4 samples.

How the data were processed

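The series holds 4 arrays of dermal fibroblast RNA from mice on a C57BL/6 background, 1 array for each of 4 groups: deletion of Rbpj in vitro, its control, deletion in vivo, and its control. Groups were taken from the sample labels. Per the labels' protocols, poly(A) RNA was copied into cDNA from a T7 oligo(dT) primer and transcribed into biotin-labelled antisense cRNA, so signal depends on the distance of a probe set from the 3' end and on RNA integrity. Whether the in vivo cells were cultured before RNA extraction was not given in the sources used here.

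The deposited table gives log2 expression values, from 2.87 to 13.79, for 45101 probe sets, with 0 missing values. The log2 scale was read from the range of the deposited values, and the software, background correction and normalization that the authors used were not given in the sources used here. The 4 columns had unequal distributions (upper quartiles 7.18, 7.17, 6.91 and 6.94), so they were quantile normalized over the 4 arrays, as fixed before the data were examined. The values as deposited served as an alternative.

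Probe sets were named from the platform annotation, which listed 35890 of them. Of these 34958 had 1 gene symbol and 932 had several, and the latter were not named. The other 9211 were unnamed here. Symbols were updated through RefSeq (assembly GRCm38.p6), where 34754 of the single-gene probe sets matched. No coordinates are given, because no genome build was named for the arrays. The 64 control probe sets were kept out of the gene table. Each gene was represented by its probe set with the highest mean over the 4 arrays. Of 18194 genes, 10916 had a mean at or above the 40th percentile (5.28 on the log2 scale) and were analysed. Dim genes lie close to the background, where a fold understates the difference.

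Within each system the difference of log2 values between the deleted and the control array was taken, and genes at least 2-fold higher or lower were counted. With 1 array per group no test was made. The deletion effect shared by the systems was fitted with limma (lmFit and eBayes) with system as a covariate, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 2 differences were compared by correlation across genes and by overlap against n1 × n2 / N.

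The 30 gene lists, with 531 entries of which 487 had a probe set, were written before the data were examined. For each list the median difference was placed among 10000 random lists of the same size matched on mean level in 20 bins, and was called outside the range below percentile 2.5 or above 97.5. These percentiles describe the arrays and are not p-values. The 4 lists with under 5 measured members (lymphocyte, mast cell, red blood cell, and X inactivation and Y-linked genes) were given values only.

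Genes named in the text followed a fixed rule. It took Rbpj, the 10 genes with the largest difference per direction and comparison among those at least 2-fold different, and the 10 per direction with the largest difference in the system where the gene moved less. Every probe set of such a gene above the level filter had to share its sign, and symbols without an informative name were skipped. From each list it took up to 4 members with the largest absolute difference per comparison. Genes named outside the rule are marked as such: Krt10, Lor, Epcam, the members of overlaps, and genes of the closing section were named after their values were seen. Gapdh, Actb, Pcx and Tfrc were read from the control probe sets at the 3' and 5' ends. Gene length was the span from first to last base in the same RefSeq table, introns included, and was found for 99.9% of the genes analysed.

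Alternatives were the values as deposited, loess normalization within each pair, centring on the median difference, the 20th percentile of linear values (15.3) added before log2, no level filter, a filter at the 60th percentile, the median of all probe sets of a gene, removal of probe sets ending in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, the list mean, a variance trend, and a model without the system term. Restricting to genes whose probe sets share a direction, and removing the trend on gene length, were chosen after seeing the data. The procedures were tested on simulated data for both comparisons, with 200 genes changed by 2 on the log2 scale and a noise SD of 0.2. The limma model recovered 100% of them and called 10 unchanged genes. The 2-fold rule, scored on the simulated in vitro pair, recovered 100% and called 4. Of unchanged lists 6% lay outside the random range. Each simulated gene changed equally in both systems, whereas the measured differences of the systems correlated weakly (r = 0.0998). The noise was also set by hand, and the planted changes were far above it and above the 2-fold threshold. The measured differences had an SD over genes of 0.40 in vitro and 0.55 in vivo. The simulation therefore checks the procedures only. It gives neither the power of the 4 arrays nor the number of false calls among their 2-fold genes. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.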

Results

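Transcript levels were measured on 4 Affymetrix mouse expression arrays, each hybridised with labelled cRNA from dermal fibroblasts, the collagen-producing cells of the skin. In the in vitro pair, the labels describe deletion of Rbpj in cells given an adenovirus with Cre recombinase, and control cells given an adenovirus with GFP. In the in vivo pair, fibroblasts came from mice with a Cre transgene labelled ColI and a floxed Rbpj gene, and the control had the floxed gene without Cre. Rbpj encodes RBP-J kappa, also called CSL, the DNA-binding protein through which Notch receptors control transcription. Each of the 4 groups had 1 array, so there are no replicates within a group, no difference within a system has a replicate check, and no p-value is given for it. The number of arrays limits the precision. Values of a gene are those of its brightest probe set, and where its probe sets differed by more than 1 on the log2 scale in the comparison described, their range is given as a technical spread. Where a signal lay under the level cutoff (log2 5.28), as named below, the size of the difference is not exact. The deposited log2 values had medians of 4.96 (in vitro, deleted), 4.94 (in vitro, control), 5.06 (in vivo, deleted) and 5.02 (in vivo, control). Arrays of one system correlated more closely (r = 0.983 in vitro, r = 0.982 in vivo, across all probe sets) than arrays of different systems (0.949 to 0.963). The bioB hybridisation spike also separated the systems, at 8.36 and 8.39 in vitro and 6.93 and 6.97 in vivo, so system and array batch cannot be told apart, while both arrays of each comparison had like spike levels.

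Rbpj itself was lower with the deletion on most of its probe sets. In vitro, the log2 difference between the deleted and the control array was -1.11 for probe set 1448957_at (2.15-fold lower), -1.34 for 1454896_at (2.53-fold lower) and 0.10 for 1418114_at. In vivo the same probe sets differed by -0.10, -0.83 and -0.49. The 5th percentile of the difference over all genes analysed was -0.74 in vitro and -0.88 in vivo. All in vivo values of Rbpj thus lay within the general spread of genes, whereas the 2 lower values in vitro lay beyond it. The mean over the 3 probe sets was -0.78 ± 0.77 in vitro and -0.48 ± 0.37 in vivo (SD over probe sets). Probe positions relative to the deleted exons were not used here, and a probe set outside them checks nothing about the deletion.

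**Figure D1:**
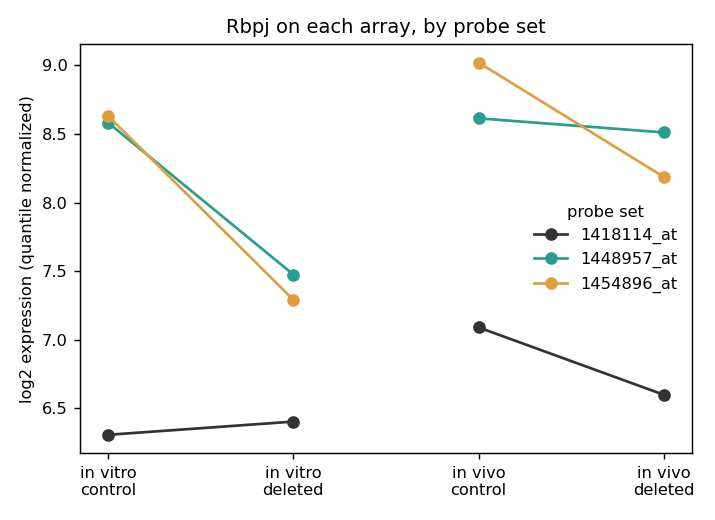
Log2 expression of Rbpj after quantile normalization on each of the 4 arrays, with 1 line per probe set joining the control and the deleted array of a system. Probe set 1454896_at was lower with the deletion in both systems (-1.34 and -0.83), whereas 1418114_at was 0.10 higher in vitro.

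The in vitro comparison asked which transcripts differ when Rbpj is deleted in fibroblasts in culture. Among genes that passed the rule for names, the largest excess in the deleted culture was that of ND5, a mitochondrially encoded subunit of respiratory complex I, at 4.72-fold. Sp3, a zinc-finger transcription factor, was 3.94-fold higher, and Rraga, a GTPase of amino acid signalling to mTORC1, was 3.71-fold higher. The receptor Axl was 2.87-fold higher. Uba3, a subunit of the NEDD8-activating enzyme, was 3.19-fold higher and the receptor Ifngr2 3.10-fold, but their probe sets ranged from 0.12 to 1.67 and from 0.30 to 1.63 on the log2 scale. Under the same rule the largest deficit was that of the probe set assigned to Snord104, a small nucleolar RNA gene (3.20-fold lower). Which transcript of that locus gave its signal in poly(A)-primed material was not tested. Next came Krt14, a keratin of basal epidermis (3.08-fold lower), and Hoxd3os1, a transcript antisense to Hoxd3 (2.92-fold lower).

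Further genes named by the same rule were Dcun1d1 (1.81 on the log2 scale), Asph (1.72, range 0.13 to 1.72), Dmd (1.71) and Ehd2 (1.55, range 0.39 to 2.41) among those higher. Among those lower were Bola2 (-1.54, with its nearest probe set to 0 at -0.58), Dnajc17 (-1.48), Mrps25 (-1.42), Ndufa5 (-1.37), Tmem256 (-1.35), Serpina10 (-1.33) and Aamdc (-1.33). With the median of all probe sets of a gene in place of the brightest, Dcun1d1 was at -0.59 and Asph at -0.15. Among the 57 genes named for the largest differences in a comparison or in both, 12 more then lost a 2-fold in vitro difference. In all, 86 of 10916 genes were at least 2-fold higher and 125 at least 2-fold lower in the deleted culture. Genes higher made up 40.8% of these, against 55.9% after centring on the median difference, 54.0% after loess normalization within the pair and 70.6% with the median of all probe sets.

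Among the gene lists fixed beforehand, Notch and CSL target genes were higher in the deleted culture, with a median log2 difference of 0.32 and 8 of 11 measured members higher, though none by 2-fold. Members included Notch3 (0.77), Myc (0.65), Hes1 (0.57), a transcriptional repressor induced by Notch, and Jag1 (0.39), a Notch ligand. Their median lay at percentile 99.9 of random lists of like expression level, and at percentile 88.2, with a median of 0.06, once probe sets with the suffixes _x_at and _s_at were left out. Structural genes of the extracellular matrix had a median of 0.27, with 22 of 26 members higher, among them Col12a1 (0.74), Ogn (0.71) and Lox (0.68, range 0.68 to 2.25), the collagen-crosslinking enzyme. Interferon-stimulated genes had a median of 0.22 (15 of 21 higher), with Oasl1 at 0.88 and Irf9 at 0.73. Keratinocyte markers had lower values (-0.39, 8 of 10 lower, Krt17 at -1.30 with its deleted signal under the cutoff, and Krt5 at -1.03). The skeletal muscle median was also below the range (-0.46), but 8 of its 12 members were under the level cutoff on at least 1 of the in vitro arrays, so no direction is read from it. It was -0.23 and within the range with the median of all probe sets. The other 21 lists with a percentile lay within the random range, including cell proliferation (-0.03), cytokines and chemokines (-0.05) and myofibroblast markers (0.04). About 1.3 of 26 lists would fall outside by chance if members varied independently. Members of a real list may vary together, so with 1 array per group more could fall outside without any effect of the deletion.

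RNA quality differed between the in vitro arrays. The 3' probe set of Gapdh exceeded the 5' probe set by 1.01 on the log2 scale in the control and by 0.04 in the deleted culture, that of Actb by 1.09 and 0.39, and that of Pcx by 3.27 and 1.94. Tfrc went the other way (0.93 in the control, 1.47 in the deleted culture), with a 5' signal near the bottom of the scale, at 3.80 and 3.74. In the in vivo arrays the excess was 0.15 and 0.12 for Gapdh, 0.37 and 0.15 for Actb and 1.09 and 0.80 for Pcx (control, deleted). Across 10902 genes, the in vitro difference followed gene length (Spearman rho = 0.258 across genes, which are not independent replicates), and the in vivo difference had a rho of -0.0392. Of the 2726 shortest genes, 71 were at least 2-fold lower and 12 higher in vitro, and of the 2726 longest 13 were lower and 34 higher. In vivo the counts were 98 lower and 88 higher among the shortest and 147 lower and 61 higher among the longest. Probe sets of a gene also differed more in vitro: of genes with several probe sets and a 2-fold difference, 64 of 93 had all probe sets in one direction, against 245 of 265 in vivo.

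**Figure D2:**
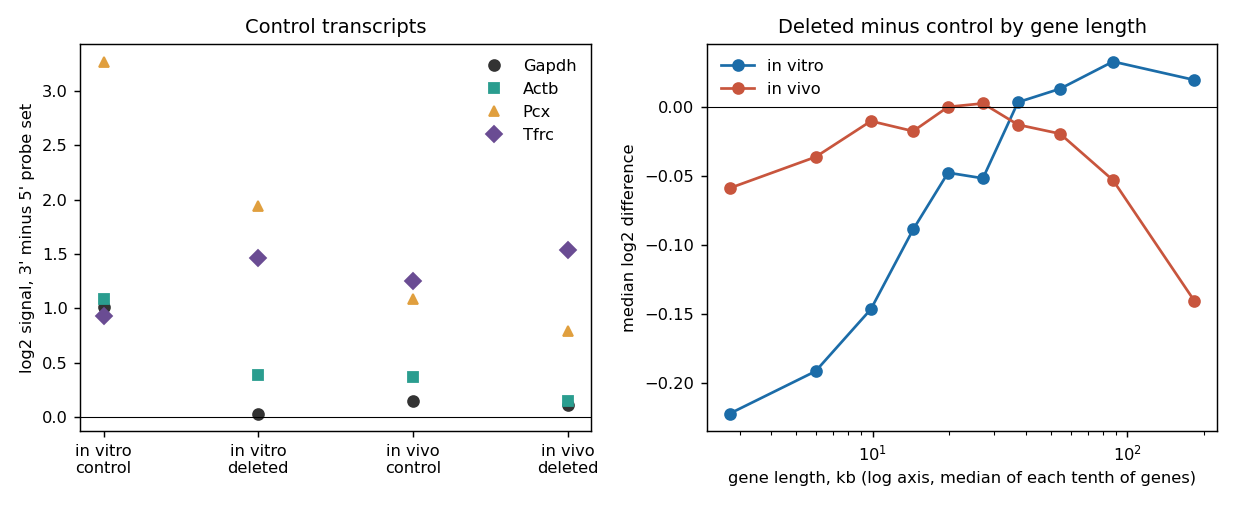
Left, log2 signal of the 3' minus the 5' probe set of 4 control transcripts on each array, where the in vitro control had the highest values for Gapdh (1.01), Actb (1.09) and Pcx (3.27) and the lowest for Tfrc (0.93). Right, median log2 difference (deleted minus control) of genes in 10 equal groups by gene length, on a log axis in kb, rising with length in vitro (rho = 0.258), with the longest group at -0.14 in vivo (rho = -0.0392).

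The in vivo comparison asked the same of fibroblasts whose Rbpj gene was deleted in the animal. Keratin genes were among those with the largest excess in the deleted array. Krt6a, a keratin of activated keratinocytes, was 39.2-fold higher (log2 5.29 to 6.22 over its 2 probe sets), and Krt14, Krt5 and Krt17 were 32.1-fold, 18.8-fold and 17.1-fold higher. The desmosomal protein Dsp was 27.0-fold higher, and Sprr1a, a cornified envelope precursor, was 15.2-fold higher. Lamb3, a laminin chain of the epidermal basement membrane, was 11.0-fold higher. Also higher were the protease inhibitor Tfpi2 (11.2-fold), the acute-phase gene Saa3 (3.32 on the log2 scale) and Ifi202b (29.3-fold), an interferon-inducible gene whose expression is known to vary between mouse strains. Whether the 2 in vivo samples differed in strain background was not tested, and such a difference could not be told apart from the deletion. The control signals of Krt17, Dsp, Sprr1a, Lamb3, Tfpi2 and Ifi202b were under the level cutoff (3.23 for Dsp to 4.89 for Sprr1a), so their folds rest on background signal.

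Among genes lower in the deleted in vivo array, Abi3bp, an extracellular matrix protein, was 15.8-fold lower (log2 -3.98 to -3.76 over 2 probe sets), and Itgbl1, an integrin-beta-like secreted protein, 12.2-fold lower. Adh1, an alcohol dehydrogenase that also oxidises retinol, was 12.1-fold lower, the ferritin receptor Scara5 10.4-fold, Egfl6 9.93-fold and the small proteoglycan Ogn 8.59-fold (log2 -4.24 to -3.10). Rtl3 (-3.42), Clca3a1 (-3.11), Reg1 (-3.06) and the heparin-binding growth factor Ptn (-3.05, range -3.79 to -1.0) completed the list. The deleted signals of Itgbl1, Scara5 and Egfl6 were under the cutoff. In all, 307 of 10916 genes were at least 2-fold higher and 416 at least 2-fold lower.

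Of the 26 gene lists with a percentile, 9 were above the random range in vivo. Keratinocyte markers had a median of 3.26, with 7 of 10 measured members at least 2-fold higher. Members with a probe set numbered 16, and those not measured fell under the level filter. The 3 members without a 2-fold difference were Krt10 (-0.33) and Lor (-0.22), genes of differentiated epidermis, and Epcam (0.07, range 0.07 to 2.62), all named after their values were seen. Skeletal muscle markers had a median of 1.66, with 10 of 12 measured members at least 2-fold higher, of 16 with a probe set. Among them were the cardiac and fetal actin Actc1 (2.99), Mylpf (2.49), Tnnc2 (2.37) and the embryonic myosin Myh3 (2.35). The filter used the mean of all 4 arrays, so a gene high only in the deleted in vivo array could pass through that array. Tnnc2, for example, read 7.89 there, 5.52 in the in vivo control, and 4.31 and 5.32 in vitro. Such passing raises the share of higher members in both lists. All in vivo differences, including those of the lists below, come from this pair, so cells of other types in the deleted sample bear on each of them. Cell proliferation genes were higher in 25 of 25 cases (median 0.93, 10 at least 2-fold), including Rrm2 (1.47) and the replication helicase subunits Mcm6 (1.41) and Mcm3 (1.34).

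Notch and CSL target genes were also above the range in vivo, at 0.31, with Ccnd1 at 1.40, Myc at 0.99, Jag1 at 0.91 and Heyl at 0.80 (control under the cutoff), and with Hes1 and Notch3 at -0.14 and -0.20. Growth factors had a median of 0.31 (9 of 16 higher), with Hbegf, an EGF receptor ligand, at 2.81, Inhba at 1.76 and Igf1 at -2.21 (range -2.21 to -0.70). Smaller medians were those of smooth muscle and pericyte markers (0.38, 4 of 7 higher), interferon-stimulated genes (0.26, 14 of 21 higher), hypoxia and glycolysis genes (0.24, 12 of 16 higher) and TGF-beta response genes (0.22, 8 of 15 higher). The mean in place of the median left smooth muscle (0.11), interferon (0.12) and TGF-beta genes (0.05) within the range, and the TGF-beta median was -0.10 with the median of all probe sets.

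Cholesterol synthesis and uptake genes showed the most uniform deficit in vivo: 15 of 15 were lower, 12 of them at least 2-fold, with a median of -1.09. Mvd, an enzyme of the mevalonate pathway, was at -2.22, Idi1 at -1.36, Nsdhl at -1.33 and Msmo1 at -1.24, whereas the list's in vitro median was 0.08. Matrix genes had a median of -0.21 and 22 of 26 members lower, led by Ogn (-3.10), Col14a1 (-3.03, range -3.03 to -1.81), Eln, the gene of elastin (-2.80, range -2.80 to -0.48), and Mfap4 (-2.39). Chondrocyte and osteoblast markers were at -0.70 (Col11a1 at -2.21), Wnt pathway genes at -0.31 and the p53 and cell cycle inhibitor list at -0.26. Within these, Lgr5 (-3.02) and the Wnt antagonist Sfrp1 (-2.70, range -3.09 to -1.36) were lower and Wnt5a (2.20) higher. Cdkn1c (-2.46) was lower and Perp, a desmosome-associated p53 target, higher (3.09, control under the cutoff), while the 2 probe sets of Trp53inp1 had opposite signs (-2.11 and 0.19). Without the level filter the Wnt median was -0.05 (percentile 36.9), and with the median of all probe sets that of chondrocyte markers was -0.05 (percentile 34.2). Matrix (-0.16) and p53 (-0.25) medians also lay within the random range with the median of all probe sets.

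The remaining lists lay within the random range in vivo, some with members far from 0 in both directions. Cytokines and chemokines had a median of 0.04, with Saa3 (3.32), Ptgs2, the inducible prostaglandin synthase (2.99), and Ccl2 (1.28) higher and Il33 (-1.45, deleted signal under the cutoff) lower, and their mean of 0.36 lay at percentile 99.8. Matrix proteases had a median of -0.10 and a mean of 0.05, with Mmp3 (2.73, control under the cutoff) and Mmp9 (1.64) higher and Adamts5 (-1.46) lower. With the 60th percentile filter the protease median was -0.30, below the range (percentile 0.37). Myofibroblast and cancer-associated fibroblast markers were at 0.09, with Actg2 at 1.73 and Lrrc15 at 1.16, and their mean of 0.15 lay at percentile 97.7, above the range. AP-1 and immediate early genes were at 0.06, with Fosl1 at 1.60 and Klf4 at -1.26. Markers of other cell types in the sample were at 0.05 for macrophages (mean -0.09), -0.24 for endothelium and 0.21 for adipocytes. Control signals of 6 of 8 macrophage and 3 of 6 endothelial genes lay below or within 1 log2 unit above the cutoff, so those medians say little. With no level filter the endothelial median was 0.23 and the adipocyte median lay at percentile 98.65, both above the range. Notch pathway components were at -0.16, BMP response genes at 0.06, complement at -0.04 (mean 0.19, Cfb at 2.47), endoplasmic reticulum and heat stress genes at -0.06 and Schwann cell and melanocyte markers at -0.0015.

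**Figure D3:**
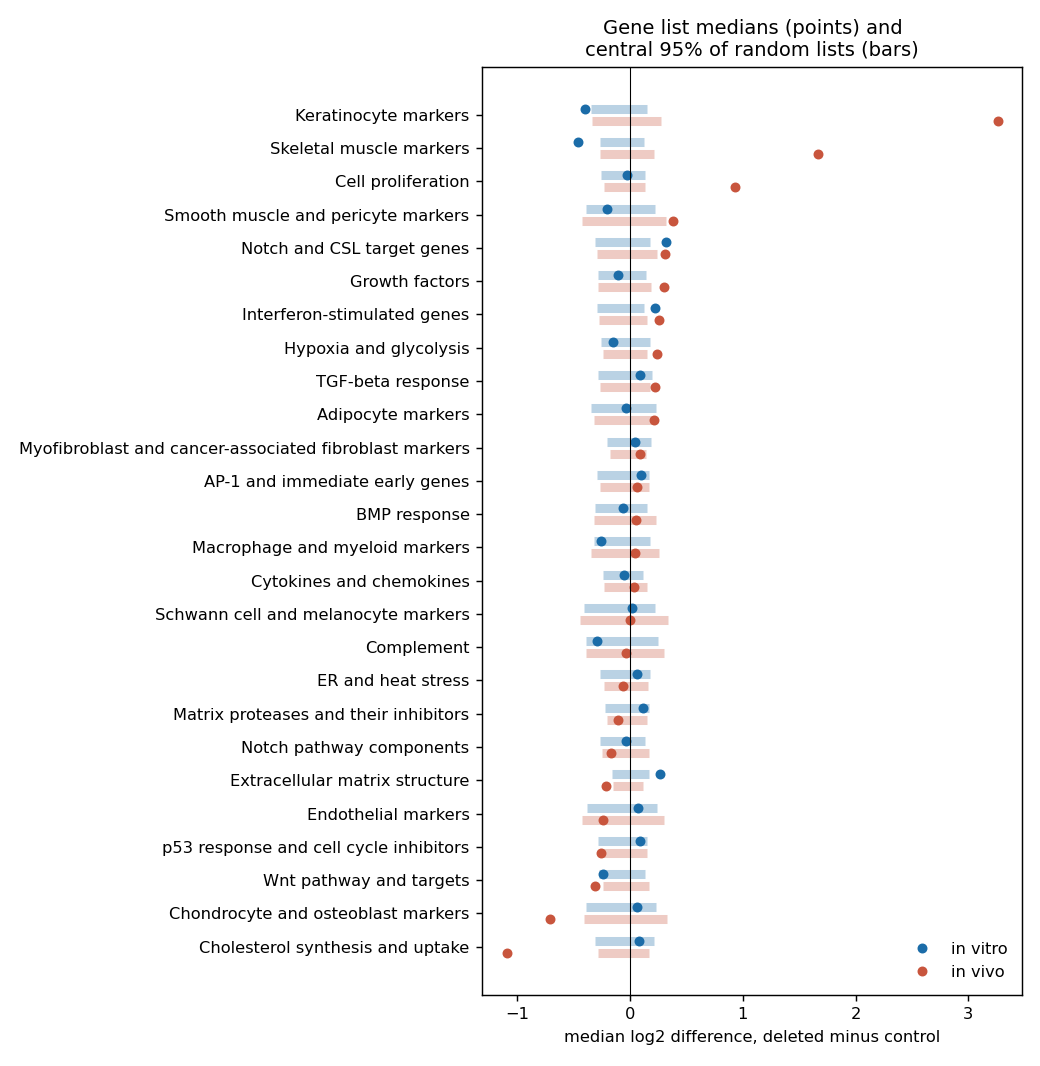
Median log2 difference (deleted minus control) of each of 26 gene lists in vitro and in vivo (points), with bars for the central 95% of medians of 10000 random lists of the same size and like expression level. In vivo, keratinocyte (3.26), skeletal muscle (1.66) and proliferation (0.93) lists lay above the bars and cholesterol synthesis (-1.09) below.

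Few genes differed by 2-fold in the same direction in both systems. Pmaip1, which encodes the proapoptotic protein NOXA, was higher by 1.40 in vitro and 1.93 in vivo, Klf10, a TGF-beta-inducible repressor, by 1.04 and 1.32, and Rbl1, a retinoblastoma relative, by 1.09 and 1.16. Has2, a hyaluronan synthase, was at 0.89 and 2.65 (range 1.60 to 2.65 in vivo). Lower in both were Hoxd3os1 (-1.55 and -1.99), Mgp, an inhibitor of calcification (-1.07 and -1.48), the membrane protease Mmp23 (-1.11 and -1.19) and Ccpg1 (-1.11 and -1.52, with a second probe set at -0.23 and -0.78). The 6 genes at least 2-fold higher in both also held Nup160, Ddias and Otub1, and 2.42 would be expected from independent lists. Ddias ranged from 0.14 to 1.52 in vitro and from -0.15 to 1.31 in vivo, and Otub1 from -0.65 to 1.09 and from 0.06 to 1.34. The 7 lower in both also held Aamdc, Pdlim2 and Gm15417, against 4.76 expected. A signal was under the cutoff in vivo for Pmaip1, Hoxd3os1, Ccpg1 and Gm15417, and in vitro for Mgp and Gm15417.

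Further genes that moved alike in both systems by the rule for names were Tpbg (1.03 and 0.97), Xpo4 (0.96 and 1.08), Tnfaip3 (0.96 and 1.01), Cav2 (1.01 and 0.91) and Kif18b (0.89 and 0.88) on the higher side. On the lower side they were Smarca1 (-0.99 and -1.21), Rab29 (-0.99 and -1.04), Synpo (-0.97 and -1.14) and C1qtnf2 (-0.97 and -1.28). Tnfaip3 and Smarca1 had a signal under the cutoff in vivo, as did Slfn5 below. Opposite 2-fold differences were seen for Aspn and Slfn5, higher in vitro and lower in vivo, and for Krt14, Krt17, Krt5, Mmp3, Saa3 and Tnnc2, lower in vitro and higher in vivo (3.28 and 3.52 genes expected). Tnnc2 had in vitro signals near the level cutoff, at 4.31 (deleted) and 5.32 (control). Across all 10916 genes the differences of the 2 systems correlated weakly (Pearson r = 0.0998, Spearman rho = 0.146), and 55.3% of genes had the same sign.

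**Figure D4:**
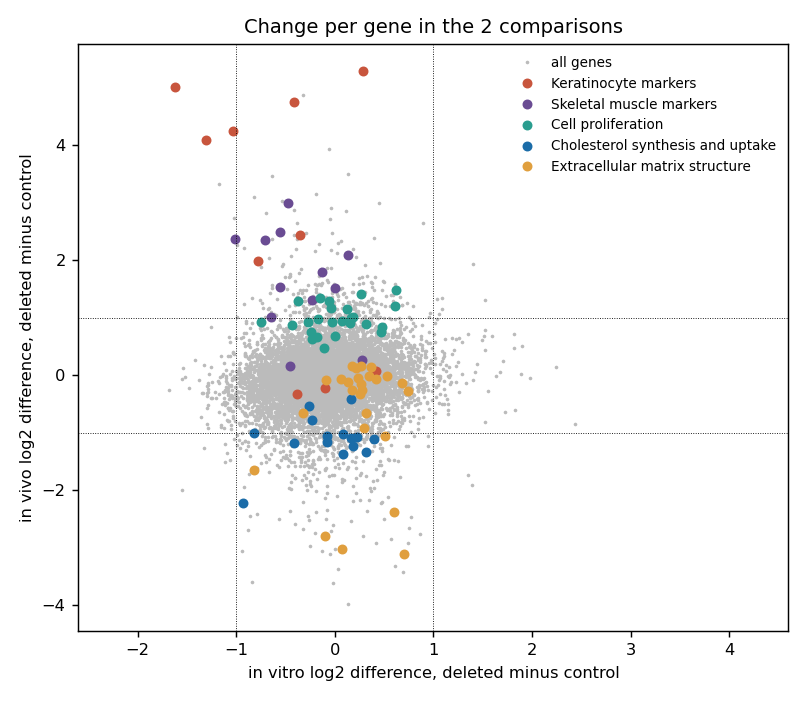
Log2 difference (deleted minus control) of each gene in vitro (horizontal) and in vivo (vertical), with members of 5 gene lists coloured and dotted lines at a 2-fold difference. Krt14 sat at -1.62 and 5.00, and the differences of all genes correlated with r = 0.0998.

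A limma model of all 4 arrays, with a term for the system, tested the deletion effect common to both systems on 1 residual degree of freedom. Hoxd3os1 (log2 -1.77 ± 0.22 SE), Pmaip1 (1.67 ± 0.23) and Aamdc (-1.30 ± 0.20) had among the smallest p-values, each with an adjusted p of 0.679 by limma with Benjamini-Hochberg adjustment and the same direction in 2 of 2 systems. No gene passed an adjusted p of 0.05. At an unadjusted p under 0.05 limma counted 759 genes, 217 higher and 542 lower, where 546 would be expected by chance. The split was 298 higher and 402 lower after centring on the median difference, and 290 and 493 after loess normalization, so its size depends on the scaling. With a variance trend limma counted 748 genes, and without the system term 131, below the 546 expected.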

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

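The tests of gene length and of a second keratinocyte list were set down before their results were seen, although the idea of a length trend came from the leading genes; the other tests in this part were chosen after the results were seen. Several results had opposite directions in the 2 systems, and with 1 array per group these differences were not tested. Keratinocyte markers had a median log2 difference of -0.39 in vitro and 3.26 in vivo, with Krt14 at -1.62 and 5.00, Krt5 at -1.03 and 4.24, and Krt17 at -1.30 and 4.09, with 1 signal of Krt17 under the level cutoff in each system. Skeletal muscle markers were at -0.46 and 1.66, with Tnnc2 at -1.01 and 2.37, but 8 of the 12 muscle genes, Tnnc2 among them, were under the level cutoff on at least 1 in vitro array, so their in vitro direction is not established. Matrix structural genes were at 0.27 and -0.21. The acute-phase gene Saa3 was at -1.18 and 3.32, and the protease gene Mmp3 at -1.02 and 2.73 (in vivo control under the cutoff).

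In the in vitro pair, many of the differences may come from unequal RNA integrity, since the control culture had the larger 3' excess for Gapdh, Actb and Pcx but not for Tfrc. Gene length, chosen as a trace of such a difference in poly(A)-primed material, correlated with the in vitro difference at rho = 0.258. That length includes introns and is not the distance of a probe set from the 3' end, so it is an indirect measure of RNA integrity. The spread between probe sets of a gene was 1.63 times that in vivo. Whether scaling set the balance of higher and lower genes was not decided: their ratio was 0.688 as reported and 1.27 after centring, which fixes the balance by construction. An effect of the deletion stays open beside these for every gene named in vitro, as it was not tested with replicates.

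For the in vivo keratinocyte pattern, the scaling of the arrays was argued against, since the lowest median under any scaling tried was 3.17. A lower share of fibroblasts, in the form that raises every other cell type alike, was not decided, although adipocyte markers rose less than keratinocyte markers. Adipocyte markers, with 1 of 10 near the cutoff, had a median of 0.21 and none above 0.82. That median lay at percentile 97.3, and at 98.65, above the range, with no level filter. The adipocyte list's median level was 9.55 in the in vitro control, so it may not mark a separate cell type and cannot decide the question. Muscle markers (1.66) were higher, and an unequal gain of other cell types stays open. Keratinocytes in the deleted sample remain a candidate source: a second list, of which 9 of 25 genes were measured, had a median of 0.32 (above the random range, 7 of 9 higher), though Cdh3 (-0.93) and Gjb2 (-0.72) were lower. Krt6a read log2 10.97 and Krt14 10.94 in the deleted array, the control signals of 8 of 10 genes of the first list and 7 of 9 of the second lay below or within 1 log2 unit above the cutoff, and the labels name no sort. Expression of these genes by the deleted fibroblasts themselves stays open and was not tested.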

How the results depend on the processing

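Removal of the length trend and the limit to genes whose probe sets share a direction were chosen after seeing the data; the other alternatives were planned. Under all of them limma found 0 genes at an adjusted p of 0.05 for the shared effect where it was run, and the correlation of the 2 differences stayed between 0.0966 and 0.112. Centring left 83 genes lower in vitro, the added 20th percentile 80 (and 3 higher in both systems), and removal of the length trend 62, with 6 lists above the range in vitro. The 60th percentile filter gave 161 genes higher in vivo, 3 higher and 3 lower in both, and 0 lists below in vitro; it tested fewer genes. No filter gave 5 lists below in vitro and 3 in vivo. The median of all probe sets gave 247 genes higher in vitro and 2 lists below in vivo, and leaving out _x_at and _s_at probe sets 10 genes higher in both. A threshold of 1.5-fold gave 557 higher and 1054 lower in vitro, 875 and 1226 in vivo, and 74 and 195 in both; 3-fold gave 13 and 2, 80 and 112, and 0 and 0. Genes whose probe sets share a direction numbered 34 higher and 30 lower in vitro, 107 and 138 in vivo, from fewer genes. Of 52 list medians, endothelial markers in vivo reversed to 0.23 with no filter and TGF-beta response in vivo to -0.10 with the median of all probe sets. Only the 57 genes named for the largest differences in a comparison or in both were followed singly. Of these, Dcun1d1 reversed to -0.59 and Asph to -0.15 in vitro with that median. A 2-fold difference was lost in 26 further cases in vitro, over 16 genes, and in 12 in vivo, over 9 genes. Of the in vitro cases, 12 came with the median of all probe sets. A 2-fold difference was gained in 8 cases in vitro and 1 in vivo. List medians left the random range in 15 further cases and entered it in 12. Cytokines and chemokines in vivo went above the range with no filter (0.13), the 60th percentile filter (0.54), the median of all probe sets (0.29) and the list mean (0.36). Those that entered it include matrix genes in vivo (-0.16) and skeletal muscle in vitro (-0.23) with the median of all probe sets, p53 genes in vivo (-0.25) there and without _x_at and _s_at probe sets, TGF-beta in vivo with no filter (0.11), and chondrocyte markers in vivo with no filter (-0.19). Except where an alternative tested fewer genes, the cause was not tested. Signal near background limits dim genes such as Dsp in the control. No replicate could be left out because each group has 1 array; the limma fit with the system term pairs the arrays within each system.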

Other observations

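The tests in this part were chosen after the results were seen. Interferon-stimulated genes separated the systems far more than the deletion did. In the control arrays their median was 2.30 on the log2 scale higher in vitro than in vivo, with 17 of 21 genes at least 2-fold higher, and in the deleted arrays 2.59, with 20 of 21. Ifit1 stood at 11.12 and 11.28 in vitro (control, deleted) and 6.72 and 6.68 in vivo, and Irf7 at 10.03 and 10.33 against 7.07 and 7.33. Complement genes were 1.37 higher and adipocyte markers 1.44 higher in the in vitro control than in the in vivo control, with Cd36, a fatty acid transporter, at 8.76 against 5.41. Both in vitro cultures had received an adenovirus, and system, virus and array batch cannot be told apart in this design.

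Xist, the RNA of X inactivation, had signal on all 4 arrays on probe set 1436936_s_at (8.62 and 9.35 in vitro, 10.18 and 10.60 in vivo, deleted then control). The Y-linked gene Eif2s3y read 5.70 and 5.97 in vitro and 3.94 and 3.75 in vivo on probe set 1417210_at. Of the lists with few members, lymphocyte markers had a median log2 difference of 0.03 in vitro and 0.01 in vivo over 3 genes, and mast cell markers -0.0085 and 0.63 over 3 genes. No red blood cell gene passed the level filter, and Xist alone represented its list (-0.72 and -0.43).

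The joint deficit of cholesterol synthesis genes in vivo was set against 3 explanations. Dilution by other cells was not decided. The sterol median was -1.09, and those of fibroblast markers and matrix genes were 0.088 and -0.21. However, 22 of 26 matrix genes were lower, with a mean of -0.67. Of 19 fibroblast markers 11 were higher, Cald1 did not differ (0), and the rest were lower, among the latter Pdgfra (-0.59). The list also holds actin genes, such as Actg2 (1.73), and muscle markers rose in the same array (1.66), so a fall could be masked. The scaling of the arrays was argued against, since the highest sterol median under any scaling was -1.06. A link to growth state, with fewer sterol transcripts where proliferation genes are higher, may hold but was not decided: the in vitro proliferation median lay at percentile 64.1 of random lists, so the in vitro pair offers no contrast in growth. An effect of the deletion in vivo stays open and was not tested with replicates.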
